A study of Homo sapiens with 12 samples.

How the data were processed

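Gene expression was profiled on 12 Illumina HT-12 v4 bead arrays, with 1 colour and 1 sample per array, in cells differentiated from human pluripotent stem cells. Total RNA was taken at day 18 with Trizol and biotin-labelled cRNA was hybridised, per the labels' protocols. The labels gave 4 groups of 3 arrays, set by the day on which Sonic hedgehog treatment began and by whether cells had been sorted for the NKX2.1::GFP reporter.

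The deposited scanner table held, for each of 47322 probes and each array, a mean bead intensity, a detection p-value and a number of beads, per the file headers. GenomeStudio was named, without a version or a role, in the submitters' processing notes. The intensity values were neither normalized nor background-subtracted by the authors, per the file headers and from the values, which all lay well above 0. The deposited detection p-value compared each probe with the negative control beads of its own array, and its steps implied 770 negative controls. Bead numbers, per the file headers, were used to describe the arrays. Another 12 columns of per-sample values, the bead standard errors, were not used here. A second table deposited by the authors held processed intensity values of the same arrays for 47303 probes, with no steps stated. From the values, these were on a linear scale, between 27.6% and 27.8% of each column lay below 0, the column medians ran from 10.7 to 10.7, and each column kept the rank order of its scanner intensities (rank correlation 1). Any centring beyond background subtraction and matching of the columns stayed unknown. This second table was used as an alternative.

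Intensities were corrected, normalized and put on the log2 scale with neqc of limma 3.58.1 (statmod 1.5.0) in R 4.3.3. That procedure fits background with the negative controls, inferred here from the detection p-values, adds an offset of 16 and applies quantile normalization. The offset compresses log2 fold changes of dim probes. Probes were kept when their detection p lay under 0.05 on at least 3 of the 12 arrays, which left 21520. Gene symbols came from the platform annotation, in which 30105 probes had 1 gene symbol, 8 had several and 17209 had none; 30066 matched the reference gene table by Entrez identifier and 0 symbols needed an update. Of the kept probes, 16107 had a single symbol and 5413 did not. For each of 12097 genes the probe with the highest mean over all arrays was tested, and 3191 genes had over 1 kept probe. A few genes of the fixed lists were not analysed here.

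A linear model of the 4 groups was fitted to all 12 arrays (lmFit, contrasts.fit and eBayes of limma), so that all comparisons shared 1 estimate of the spread for each gene. The 6 contrasts were each SHH group against No_SHH and the SHH groups against each other. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was said to have risen, fallen or changed when its adjusted p lay under 0.05. Errors of log2 fold changes are moderated standard errors. A gene none of whose probes was above background on any array of a group was given a lower bound in place of its fitted fold change.

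Gene lists for cell types, brain regions and pathways, 27 in number, were tested with camera of limma at a preset correlation of 0.01 between genes when at least 3 members had been measured. Their p-values were adjusted over the 26 lists that qualified, and the test was repeated with a correlation estimated from each list. The repeat's adjusted p is given where a reported call ended and for some calls that held. It was far larger for several calls that held, so very small camera p-values rest on the preset correlation. Genes were named by a fixed rule: in each comparison the 8 with the largest rise and the 8 with the largest fall among changed genes whose groups did not overlap, up to 3 changed members per direction of each list described, and a short set of patterning genes whatever their result. The groups, comparisons, gene lists, naming rule and all but 2 of the alternatives were chosen before the data were examined. Another 7 gene groups, the 2 remaining alternatives and the tests of explanations for single patterns were chosen afterwards.

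The procedure was tested on simulated data made from the real arrays for SHH_2_to_18 against No_SHH, in which 13918 genes passed the filter. Of 100 genes changed by 2-fold, 51 were recovered, and of 100 changed by 4-fold, 88, with 0 called in the wrong direction. Among 13718 unchanged genes, 2 were called, and 0 were called in a simulated SHH_10_to_18 against SHH_6_to_18 comparison without any change. None of 27 lists of unchanged genes was called, and a list of 20 changed genes had an adjusted p of 6.92e-34. The simulated noise was drawn independently for each gene, so these list results cannot show how often lists of correlated genes are called without a change.

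Alternatives covered other background corrections and offsets, median scaling and cyclic loess in place of quantile normalization, the authors' processed values, no filter and a stricter filter on dim probes, other ways to treat several probes of a gene, array weights, a trended and robust variance, the replicate number as a block, fits of only the groups compared, each array left out in turn, and other list tests. Those added afterwards left out the 2 arrays of lowest mean signal, and NKX2-1 from the list that held it. For comparisons that shared the No_SHH arrays, 100 sets of unchanged groups were simulated against shared controls. Figures were drawn with matplotlib in Python 3.11.15. The number of arrays limits the precision of every value.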

Results

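Gene expression was measured by bead array at day 18 of differentiation in cells derived from human pluripotent stem cells, in 4 groups of 3 arrays. In 3 groups, Sonic hedgehog (SHH), the secreted morphogen that patterns the ventral neural tube, was supplied from day 2, day 6 or day 10 until day 18. They are named SHH_2_to_18, SHH_6_to_18 and SHH_10_to_18, and their cells were sorted by FACS for green fluorescence from an NKX2.1::GFP reporter. NKX2-1 is a transcription factor of ventral forebrain progenitors, from which cortical interneurons and parts of the hypothalamus arise. The remaining group, No_SHH, received no SHH, and its cells were left unsorted because, per the labels, none expressed GFP. The series concerned directed differentiation into cortical interneurons.

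Mean signal per array ran from 207 to 336 intensity units against medians of 94.6 to 120, and 16971 to 19656 of 47322 probes per array (35.9% to 41.5%) were above background. Across genes, normalized log2 values of arrays within a group correlated at 0.974 to 0.984, and those of different groups at 0.924 to 0.976. The labels call the arrays biological replicates without naming separate cultures, so p-values measure the spread between these samples, which may be technical in part. The first principal component, with 37.3% of the variance, set No_SHH (41.9 to 44.6) apart from SHH_10_to_18 (-3.43 to -2.77), SHH_2_to_18 (-17.3 to -16.1) and SHH_6_to_18 (-24.8 to -21.6). The second, with 20.1%, set SHH_10_to_18 (28.8 to 32.1) apart from SHH_2_to_18 (-21.6 to -19.4).

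**Figure D1:**
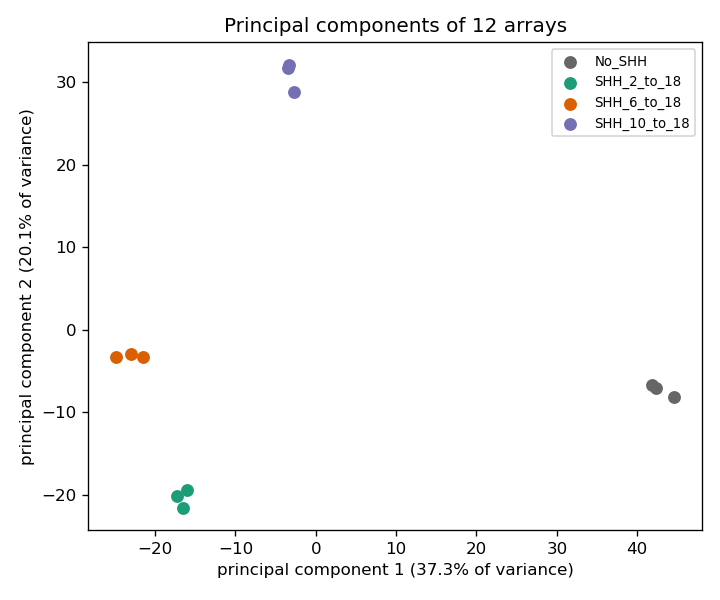
Scores of the 12 arrays on the first and second principal components of normalized log2 expression, in log2 units, with 1 point per array coloured by group. The 3 arrays of each group lie close together, with No_SHH between 41.9 and 44.6 on the first component and SHH_10_to_18 between 28.8 and 32.1 on the second.

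SHH_2_to_18, which was sorted, was compared with unsorted No_SHH to show what differed after the longest SHH exposure together with the sort. NKX2-2, a homeodomain factor of the ventral-most neural tube, was at least 65.9-fold higher (adjusted p = 1.05e-14, limma, 3 arrays per group). FOXA2, a forkhead factor of the floor plate, was at least 48.8-fold higher (adjusted p = 1.05e-14). PTCH1, the SHH receptor and a direct target of the pathway, was at least 12.4-fold higher (adjusted p = 1.85e-11). SP8, a zinc-finger factor of the lateral and caudal eminences, was at least 29.6-fold lower (adjusted p = 1.66e-13). EMX2, a homeobox gene of the dorsal telencephalon, fell by 4.51 ± 0.22 (SE) on the log2 scale (adjusted p = 1.9e-11), with its probe above background on 2 of 3 SHH_2_to_18 arrays. Where all of a gene's probes were not well above background on any array of a group, "at least" sets the bright group's mean of normalized log2 values against a floor. That floor is the dim group's mean of, for each array, the higher of the lowest signal among probes well above background and the dim probe's own signal.

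Among other genes with the largest rises, SFTA3, a gene next to NKX2-1, was at least 29.3-fold higher (adjusted p = 1.57e-12) and GRP, which encodes gastrin-releasing peptide, at least 23.9-fold (adjusted p = 1.47e-13). NKX2-1 itself was at least 20.6-fold higher (adjusted p = 6.99e-14), but cells had been sorted on its reporter, so its level in the sorted groups is no finding in any comparison with No_SHH. COL8A1, a short-chain collagen, rose by 4.83 ± 0.18 (adjusted p = 3.67e-13) and POU3F1, a POU-domain factor, by 4.81 ± 0.19 (adjusted p = 5.8e-13). Neither has a bound, because another probe of the gene was detected in No_SHH. Large falls were measured for the retinoic acid synthesis enzymes ALDH1A1 (at least 23.7-fold lower, adjusted p = 1.51e-12) and ALDH1A3 (at least 10.6-fold, adjusted p = 1.25e-10). PAX6, a regulator of dorsal telencephalon and eye, fell by 4.11 ± 0.23 (adjusted p = 1.45e-10; above background on 1 of 3 SHH_2_to_18 arrays). PCDH19, a protocadherin, was at least 9.84-fold lower (adjusted p = 1.85e-11) and LPAR4, a lysophosphatidic acid receptor, at least 9.14-fold (adjusted p = 9.77e-11).

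Of 7 measured hedgehog targets, 4 rose, 0 fell and 3 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 3.37e-06). GLI1, a transcriptional target and effector of the pathway, differed by 0.31 ± 0.20 (adjusted p = 0.336). All 4 measured pathway genes that hedgehog signalling represses fell (4 adjusted over the list alone, camera adjusted p = 4.18e-07). Among them, the co-receptor gene GAS1 fell by 3.97 ± 0.26 (adjusted p = 1.03e-09) and the repressor gene GLI3 fell by 2.57 ± 0.21 (adjusted p = 2.18e-08; above background on 1 of 3 SHH_2_to_18 arrays). GLI2 was at least 2.28-fold lower (adjusted p = 5.74e-06). In the floor plate list, 3 of 5 members rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.00113). FOXA1 rose by 2.43 ± 0.24 (adjusted p = 3.39e-07; above background on 2 of 3 No_SHH arrays). The secreted floor plate protein gene SPON1 rose by 2.28 ± 0.20 (adjusted p = 6.72e-08), and the sulfatase gene SULF1 fell by 1.95 ± 0.18 (adjusted p = 2.08e-07). The oligodendrocyte precursor list, which shares NKX2-2 with the hedgehog targets, rose in 3 of 4 members and fell in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 5.58e-06). In it, OLIG2 was at least 3.73-fold higher (adjusted p = 8.81e-06).

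In the list for the medial ganglionic eminence (MGE) and cortical interneuron lineage, 3 of 12 members rose, NKX2-1 among them, and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.00333). Without NKX2-1, a test added after seeing the data, the call ended (adjusted p = 0.0586), with the list's mean at 0.40 in place of 0.79 and its median at 0.40 in place of 0.41. LHX6, a factor of interneuron precursors leaving the MGE, differed by 0.42 ± 0.22 (adjusted p = 0.218). DLX2, which specifies GABAergic progenitors, differed by -0.00 ± 0.22 (adjusted p = 1), while DLX5 fell by 1.13 ± 0.22 (adjusted p = 0.00125). Probes of LHX8 and of SHH lay below the detection filter. Of 11 hypothalamic genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.261). SIX6, a homeobox gene of hypothalamus and retina, rose by 4.05 ± 0.17 (adjusted p = 2.04e-12) and RAX, which marks hypothalamus and eye field, by 2.04 ± 0.28 (adjusted p = 1.88e-05). OTX2, a forebrain homeobox gene, fell by 2.22 ± 0.18 (adjusted p = 2.69e-08). The eye field list, which holds SIX6 and RAX too, rose in 3 of 7 members and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.00134). Dorsal telencephalic genes fell in 8 of 13 and rose in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 6.96e-09). SLC17A6, a vesicular glutamate transporter, was at least 3.57-fold lower (adjusted p = 2.01e-09). Of 9 genes of the lateral and caudal eminences, 2 rose and 5 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.0573 with an estimated correlation).

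Postmitotic neuron genes rose in 12 of 19 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 7.52e-08, median log2 fold change 0.73). The secretogranin SCG3 rose by 2.96 ± 0.18 (adjusted p = 3.19e-10) and the RNA-binding ELAVL4 by 2.13 ± 0.18 (adjusted p = 4.62e-08). Hypoxia and glycolysis genes rose in 9 of 12 and fell in 0 (11 and 0 adjusted over the list alone, camera adjusted p = 3.09e-10, median 1.30). Adrenomedullin, ADM, rose by 2.37 ± 0.17 (adjusted p = 4.02e-09). Of 7 GABAergic neuron genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.972). GAD1, an enzyme of GABA synthesis, rose by 1.33 ± 0.19 (adjusted p = 2.91e-05), and RELN, which encodes reelin, was at least 3.03-fold lower (adjusted p = 3.83e-09). The median of that list was 0.33, but its mean (-0.15) and test pointed down. Of 20 cell cycle genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.321). In the mesenchyme list, 1 of 11 rose and 4 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.117 with an estimated correlation). In the epithelium list, 0 of 7 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.00988, adjusted p = 0.175 with an estimated correlation).

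In total, 1145 genes rose and 870 fell in SHH_2_to_18, and the groups did not overlap for 4043 genes (33.4%, where chance gives 10%). SHH treatment and cell sorting went together and cannot be told apart in comparisons with No_SHH. Immediate early and dissociation stress genes, which can respond to sorting, rose in 10 of 13 and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.36e-08, median 1.00). FOS rose by 4.26 ± 0.21 (adjusted p = 1.85e-11; above background on 2 of 3 No_SHH arrays) and EGR1 by 3.79 ± 0.18 (adjusted p = 1.17e-11). Median scaling of the arrays gave 1130 changed genes in place of 2015. The epithelium list lost its call when all probes were tested (adjusted p = 0.0664) and the eye field list without a filter on dim probes (adjusted p = 0.184), and the call of GAD1 was lost under 1 of the settings tried.

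SHH_6_to_18, also sorted, was compared with unsorted No_SHH to show what differed after SHH from day 6 together with the sort. NKX2-2 was at least 61.4-fold higher (adjusted p = 1.96e-14, limma, 3 arrays per group), FOXA2 at least 30.2-fold (adjusted p = 9.63e-14) and PTCH1 at least 14.8-fold (adjusted p = 7.07e-12). The basic helix-loop-helix genes OLIG1 and OLIG2, of ventral progenitors and the oligodendrocyte lineage, were at least 11.0-fold (adjusted p = 7.26e-11) and 9.57-fold higher (adjusted p = 1.01e-08). ALDH1A1 was at least 23.4-fold lower (adjusted p = 1.44e-12), and EMX2 fell by 4.87 ± 0.22 (adjusted p = 6.4e-12; above background on 1 of 3 SHH_6_to_18 arrays).

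The metalloproteinase MMP7 was at least 16.9-fold higher (adjusted p = 1.03e-12), NKX2-1, the sorted gene, at least 13.9-fold (adjusted p = 6.26e-13) and GRP at least 13.8-fold (adjusted p = 1.44e-12). COL8A1 rose by 4.79 ± 0.18 (adjusted p = 6.26e-13) and POU3F1 by 4.52 ± 0.19 (adjusted p = 1.44e-12), again without a bound. SP8 fell by 4.60 ± 0.19 (adjusted p = 1.44e-12) and PAX6 by 3.86 ± 0.23 (adjusted p = 2.85e-10; above background on 2 of 3 SHH_6_to_18 arrays). The tight junction gene CLDN1 was at least 11.5-fold lower (adjusted p = 1.16e-11), ALDH1A3 10.5-fold (adjusted p = 8.05e-11), PCDH19 9.70-fold (adjusted p = 1.47e-11) and LPAR4 9.01-fold (adjusted p = 6.56e-11). LHX6 differed by 0.26 ± 0.22 (adjusted p = 0.442), DLX2 by -0.25 ± 0.22 (adjusted p = 0.483) and RAX by 0.35 ± 0.28 (adjusted p = 0.41). GLI1 rose by 0.69 ± 0.20 (adjusted p = 0.02; above background on 1 of 3 No_SHH arrays).

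Of 7 hedgehog targets, 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 8.58e-07). The 4 repressed pathway genes all fell (4 adjusted over the list alone, camera adjusted p = 2e-05), GAS1 by 3.67 ± 0.26 (adjusted p = 3.11e-09). All 4 oligodendrocyte precursor genes rose (4 adjusted over the list alone, camera adjusted p = 8.92e-09). Of 13 dorsal telencephalic genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone, camera adjusted p = 1.73e-07). In the MGE and interneuron list, 3 of 12 rose, NKX2-1 among them, and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0834). MAF, a factor of MGE-derived interneurons, rose by 1.12 ± 0.20 (adjusted p = 0.000429). Of 11 hypothalamic genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.192). SIX6 rose by 4.12 ± 0.17 (adjusted p = 1.48e-12) and OTP, a homeobox gene of neuroendocrine hypothalamus, by 1.82 ± 0.22 (adjusted p = 4.89e-06). For the eye field list, 3 of 7 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00777, adjusted p = 0.0509 with an estimated correlation).

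Of 19 postmitotic neuron genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 3.21e-10, median 0.96). SCG3 rose by 2.99 ± 0.18 (adjusted p = 2.44e-10) and ELAVL4 by 2.59 ± 0.18 (adjusted p = 2.77e-09). GABAergic neuron genes rose in 4 of 7 and fell in 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.168). SST, the interneuron peptide somatostatin, rose by 2.78 ± 0.24 (adjusted p = 5.93e-08) and GAD1 by 2.44 ± 0.19 (adjusted p = 9.72e-09). The neuropeptide Y gene NPY fell by 3.25 ± 0.22 (adjusted p = 1.98e-09; above background on 1 of 3 SHH_6_to_18 arrays). Cell cycle genes fell in 9 of 20 and rose in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.000239, adjusted p = 0.0529 with an estimated correlation, median -0.47). CCNA2, which encodes cyclin A, fell by 1.01 ± 0.18 (adjusted p = 0.000361). Epithelial genes fell in 6 of 7 and rose in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 2.14e-07). Among them were the keratin KRT19 (-2.60 ± 0.22, adjusted p = 4.06e-08) and E-cadherin, CDH1 (-2.24 ± 0.19, adjusted p = 3.58e-08). Of 12 hypoxia and glycolysis genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.0529 with an estimated correlation, median 0.47). Of 14 neural progenitor genes, 6 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.0529 with an estimated correlation). The Notch effector HES1 rose by 2.28 ± 0.17 (adjusted p = 4.92e-09), and PROM1, which encodes the progenitor surface protein prominin, fell by 2.00 ± 0.19 (adjusted p = 2.07e-07).

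In total, 1404 genes rose and 1199 fell in SHH_6_to_18, with no overlap between the groups for 4304 genes (35.6%, where chance gives 10%). Sorting and treatment cannot be told apart here either. Immediate early and dissociation stress genes rose in 6 of 13 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.000977, median 0.37). FOS rose by 3.79 ± 0.21 (adjusted p = 7.78e-11; above background on 2 of 3 No_SHH arrays) and EGR1 by 3.30 ± 0.18 (adjusted p = 7.21e-11). Median scaling gave 1524 changed genes in place of 2603 and 41.2% of them higher in place of 53.9%, and the call of GLI1 was lost under 8 of the settings tried. The eye field list lost its call without a filter on dim probes (adjusted p = 0.211).

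SHH_10_to_18, also sorted, was compared with unsorted No_SHH to show what differed after the latest and shortest exposure together with the sort. FOXA2 and NKX2-2 were each at least 11.2-fold higher (adjusted p = 1.71e-11 and 3.2e-11, limma, 3 arrays per group). OLIG1 was at least 10.8-fold higher (adjusted p = 1.33e-10), OLIG2 at least 9.73-fold (adjusted p = 1e-08) and PTCH1 at least 8.24-fold (adjusted p = 2.09e-10). CDH1 fell by 3.45 ± 0.19 (adjusted p = 1.33e-10), KRT19 by 2.97 ± 0.22 (adjusted p = 6.56e-09) and COL1A1, the main fibrillar collagen, by 2.92 ± 0.18 (adjusted p = 6.55e-10). GRP was not well above background in either group.

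NKX2-1, on which cells were sorted, was at least 18.7-fold higher (adjusted p = 3.54e-13) and SFTA3 at least 15.6-fold (adjusted p = 4.28e-11). SPARCL1, a matricellular protein gene of glia and neurons, rose by 4.21 ± 0.21 (adjusted p = 3.3e-11; no bound, since another of its probes was detected in No_SHH). The FGF pathway inhibitor gene SPRY4 rose by 3.68 ± 0.18 (adjusted p = 3.33e-11; above background on 2 of 3 No_SHH arrays). EMX2 fell by 4.67 ± 0.22 (adjusted p = 3.05e-11) and ALDH1A1 by 4.59 ± 0.21 (adjusted p = 1.71e-11), each above background on 1 of 3 SHH_10_to_18 arrays. CLDN1 was at least 11.6-fold lower (adjusted p = 1.71e-11), MAMDC2 9.92-fold (adjusted p = 1.16e-09) and NPY 9.46-fold (adjusted p = 4.99e-10). LRATD2 fell by 3.52 ± 0.28 (adjusted p = 2.23e-08). WLS, which carries WNT proteins to the cell surface, fell by 3.32 ± 0.32 (adjusted p = 3.21e-07; above background on 2 of 3 SHH_10_to_18 arrays). PAX6 fell by 2.85 ± 0.23 (adjusted p = 2.55e-08) and GLI1 rose by 1.54 ± 0.20 (adjusted p = 1.8e-05; above background on 1 of 3 No_SHH arrays). LHX6 (-0.12 ± 0.22, adjusted p = 0.792), DLX2 (0.06 ± 0.22, adjusted p = 0.905) and RAX (-0.12 ± 0.28, adjusted p = 0.829) did not pass.

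Hedgehog targets rose in 6 of 7 and fell in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 8.24e-12, adjusted p = 0.00666 with an estimated correlation). All 4 oligodendrocyte precursor genes rose (4 adjusted over the list alone, camera adjusted p = 3.07e-09). Of the 4 repressed pathway genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0715). Dorsal telencephalic genes fell in 7 of 13 and rose in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 2.16e-06). Epithelial genes fell in 6 of 7 and rose in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 8.24e-12, adjusted p = 0.0122 with an estimated correlation). Mesenchymal genes fell in 6 of 11 and rose in 0 (6 and 1 adjusted over the list alone, camera adjusted p = 2.92e-05). Of 19 postmitotic neuron genes, 4 rose and 9 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.0622 with an estimated correlation, median -0.52). The growth cone gene GAP43 fell by 1.71 ± 0.20 (adjusted p = 4.1e-06) and the stathmin STMN4 by 1.51 ± 0.24 (adjusted p = 0.000135), while SCG3 rose by 1.48 ± 0.18 (adjusted p = 4.8e-06). In the MGE and interneuron list 3 of 12 rose, NKX2-1 among them, and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.282). Among hypothalamic genes, 3 of 11 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.524, median -0.10, mean 0.33 and test upward). Progenitor genes rose in 5 of 14 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.0622 with an estimated correlation), HES1 by 2.37 ± 0.17 (adjusted p = 3.08e-09). Of 20 cell cycle genes, 0 changed with limma, 8 of them at an unadjusted p under 0.05 (camera adjusted p = 0.282). Of 12 hypoxia and glycolysis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.661).

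In total, 909 genes rose and 864 fell in SHH_10_to_18, and the groups did not overlap for 3854 genes (31.9%, where chance gives 10%). Again treatment and sorting cannot be told apart. Immediate early and dissociation stress genes rose in 5 of 13 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.0903 with an estimated correlation, median 0.14). FOS rose by 3.72 ± 0.21 (adjusted p = 1.59e-10; above background on 2 of 3 No_SHH arrays) and EGR1 by 3.25 ± 0.18 (adjusted p = 1.44e-10). Median scaling gave 1002 changed genes in place of 1773. The immediate early list lost its call with the authors' processed values (adjusted p = 0.0564), no filter on dim probes (0.137), the mean of a gene's probes (0.0514) or only the 2 groups compared (0.0601), and without SHH_10_to_18 replicate 1 (0.0526) or 2 (0.0722), No_SHH replicate 1 (0.0522) or the 2 arrays of lowest mean signal (0.0503).

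The 3 comparisons with No_SHH shared many changed genes. SHH_2_to_18 and SHH_6_to_18 had 829 genes higher and 621 lower in common and 9 in opposite directions; independent lists would share 133 and 86.2. SHH_6_to_18 and SHH_10_to_18 shared 594 higher and 543 lower, with 28 opposite, against 105.5 and 85.6 for independent lists. SHH_2_to_18 and SHH_10_to_18 shared 472 higher and 417 lower, with 57 opposite, against 86.0 and 62.1. Across all 3, 424 genes were higher and 368 lower throughout, and 29 changed in all 3 with mixed signs. Simulated unchanged groups against shared controls gave on average 0, 0 and 0.01 shared genes. Without real changes hardly any gene is called, so these counts cannot show how many shared calls common controls add among changed genes. Across genes, which are not independent replicates, log2 fold changes had a covariance of 0.299, 0.252 and 0.201 in that order against 0.023 in simulation, and a correlation of 0.84, 0.74 and 0.63 against 0.50. The simulated groups held no change, so their correlation comes from the shared controls alone. It is no reference for groups that hold real changes. The 3 control arrays do not divide into sets of at least 2 and were not split, so part of the excess of shared genes over independent lists may come from sharing them. All 3 SHH groups were sorted and No_SHH was not, so sorting was common to the 3 comparisons as well. A shared response to SHH cannot be told apart from a shared effect of sorting. Median scaling reduced the genes shared in 1 direction from 1450 to 820, from 1137 to 649 and from 889 to 485.

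**Figure D2:**
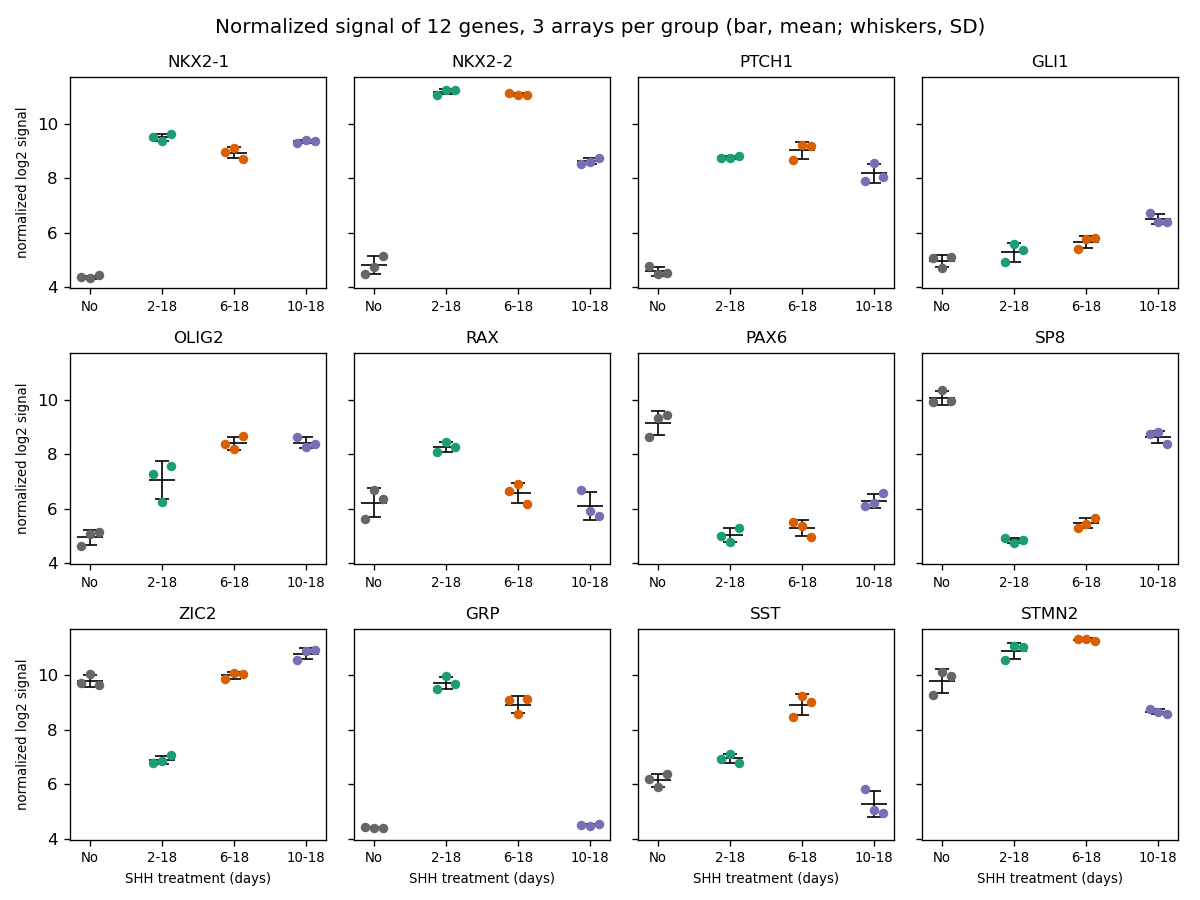
Normalized log2 expression of 12 named genes in the 4 groups; points are arrays, bars are group means and whiskers are standard deviations over 3 arrays. NKX2-2 was at least 61.4-fold above No_SHH in SHH_6_to_18 and at least 11.2-fold in SHH_10_to_18, and GRP was not well above background in No_SHH or SHH_10_to_18.

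SHH_6_to_18 was compared with SHH_2_to_18, both sorted, to show what differed with a start at day 6 in place of day 2. Every window ended at day 18, so a later start was also a shorter exposure. Start day and exposure length cannot be told apart in any comparison between windows. ZIC2, a zinc-finger gene of dorsal and midline forebrain, rose by 3.09 ± 0.18 (adjusted p = 6.83e-09, limma, 3 arrays per group), and OLIG1 by 2.80 ± 0.21 (adjusted p = 3.43e-07). SST rose by 1.98 ± 0.24 (adjusted p = 5.12e-05) and GAD1 by 1.10 ± 0.19 (adjusted p = 0.0018, lost under 1 of 26 settings), and GAD2 was at least 2.11-fold higher (adjusted p = 0.000246). The floor plate factor gene FOXA1 fell by 2.15 ± 0.24 (adjusted p = 2.23e-05), RAX by 1.69 ± 0.28 (adjusted p = 0.00124) and CDH1 by 1.99 ± 0.19 (adjusted p = 2.33e-06).

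The adhesion molecule gene NTM rose by 2.91 ± 0.26 (adjusted p = 1.33e-06) and NKX6-2, a homeobox gene of ventral progenitors, by 2.22 ± 0.21 (adjusted p = 2.33e-06; above background on 1 of 3 SHH_2_to_18 arrays). Rises also came in the lens crystallin CRYBA1, by 2.10 ± 0.22 (adjusted p = 1.05e-05), the interferon-induced IFIT1, by 2.08 ± 0.19 (adjusted p = 1.33e-06) and NDP, which encodes the WNT receptor ligand norrin, by 2.05 ± 0.18 (adjusted p = 1.33e-06). FGF19 was at least 3.03-fold higher (adjusted p = 6.9e-07). Falls were measured for CFAP95 (-2.21 ± 0.27, adjusted p = 5.09e-05), LRRN3 (-2.16 ± 0.18, adjusted p = 6.9e-07), CAPN6 (-1.88 ± 0.17, adjusted p = 1.51e-06) and the proline dehydrogenase PRODH (-1.78 ± 0.20, adjusted p = 2.23e-05). AGR3 fell by 1.82 ± 0.28 (adjusted p = 0.00081; above background on 2 of 3 SHH_6_to_18 arrays), and MAL2 was at least 3.18-fold lower (adjusted p = 4.98e-05). OLIG2 rose by 1.36 ± 0.27 (adjusted p = 0.00584, lost under 2 of 26 settings). The hedgehog targets NKX2-2 (-0.10 ± 0.18, adjusted p = 0.867), PTCH1 (0.26 ± 0.20, adjusted p = 0.622) and GLI1 (0.37 ± 0.20, adjusted p = 0.426) did not pass. Nor did NKX2-1 (-0.57 ± 0.17, adjusted p = 0.0848), PAX6 (0.25 ± 0.23, adjusted p = 0.695), LHX6 (-0.16 ± 0.22, adjusted p = 0.815) or DLX2 (-0.25 ± 0.22, adjusted p = 0.685). The PAX6 probe was above background on 2 of 3 SHH_6_to_18 and 1 of 3 SHH_2_to_18 arrays. The other kept probe of NKX2-1 fell by 1.18 ± 0.21 (adjusted p = 0.00256 over all kept probes).

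Of 7 GABAergic neuron genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.00295). Oligodendrocyte precursor genes rose in 3 of 4 and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 1.17e-05). Epithelial genes fell in 4 of 7 and rose in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 2.11e-07), KRT19 by 1.19 ± 0.22 (adjusted p = 0.00359). Hypoxia and glycolysis genes fell in 3 of 12 and rose in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 2.08e-08, median -0.60). The collagen hydroxylase gene P4HA1 fell by 0.89 ± 0.18 (adjusted p = 0.00946, lost under 3 of 26 settings). Immediate early genes fell in 4 of 13 and rose in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 1.1e-05, median -0.49). Of 20 cell cycle genes, 0 rose and 1 fell, the checkpoint kinase gene BUB1 (-0.83 ± 0.18, adjusted p = 0.0157, lost under 5 of 26 settings tried), against 7 falls adjusted over the list alone (camera adjusted p = 2.64e-05, median -0.43). In the floor plate list 1 of 5 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.145 with an estimated correlation). Of 19 postmitotic neuron genes, 1 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0185, adjusted p = 0.0588 with an estimated correlation). The neurofilament gene NEFM rose by 1.64 ± 0.20 (adjusted p = 5.3e-05). Hedgehog targets did not shift as a list, with 0 of 7 rising and 1 falling (1 and 1 adjusted over the list alone, camera adjusted p = 0.876). Of 12 MGE and interneuron genes 1 rose and 0 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.186). Of 13 dorsal telencephalic genes, 0 changed with limma, 2 of them at an unadjusted p under 0.05 (0 and 1 adjusted over the list alone, camera adjusted p = 0.863).

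In total, 141 genes rose and 197 fell in SHH_6_to_18, the fewest of the 6 comparisons, with no overlap for 2381 genes (19.7%, where chance gives 10%). The count of 338 became 161 with median scaling (28.6% higher in place of 41.7%), 511 with a background correction that used no controls, 128 without the 2 arrays of lowest mean signal, 179 and 219 without SHH_2_to_18 replicate 1 or 2, and 224 without SHH_6_to_18 replicate 1. The floor plate list lost its call with the authors' processed values (adjusted p = 0.0632), without a filter on dim probes (0.193) and without SHH_2_to_18 replicate 3 (0.0695), SHH_6_to_18 replicate 1 (0.0591) or SHH_6_to_18 replicate 2 (0.07), and the neuron list with median scaling (0.0513).

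SHH_10_to_18 was compared with SHH_6_to_18 to show what a further delay to day 10 changed. The stathmin STMN2 fell by 2.65 ± 0.21 (adjusted p = 9.25e-08, limma, 3 arrays per group) and GAP43 fell by 2.58 ± 0.20 (adjusted p = 7.48e-08). SST fell by 3.65 ± 0.24 (adjusted p = 7e-09; above background on 1 of 3 SHH_10_to_18 arrays), and GRP was at least 13.4-fold lower (adjusted p = 1.72e-11). SP8 rose by 3.17 ± 0.19 (adjusted p = 1.97e-09) and MEIS2, a homeobox gene of the lateral eminence, by 2.54 ± 0.22 (adjusted p = 3.31e-07). The list of the lateral and caudal eminences, which holds both, did not pass. In it, 3 of 9 members rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.123). NKX2-2 fell by 2.46 ± 0.18 (adjusted p = 3.81e-08) and FOXA2 by 1.43 ± 0.18 (adjusted p = 3.01e-05).

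Among further rises were those of PCDH19 (at least 4.85-fold, adjusted p = 7e-09), the noncoding LINC01551 (2.32 ± 0.20, adjusted p = 2.93e-07; above background on 2 of 3 SHH_6_to_18 arrays) and MOXD1 (2.14 ± 0.28, adjusted p = 4.39e-05). So were those of LMO3 (1.97 ± 0.16, adjusted p = 1.59e-07), SMOC1 (1.96 ± 0.26, adjusted p = 3.61e-05) and SOX21 (1.90 ± 0.18, adjusted p = 6.98e-07). Further falls were those of MMP7 (-4.14 ± 0.18, adjusted p = 2.51e-11), A2M (-3.09 ± 0.19, adjusted p = 2.15e-09) and the ephrin receptor EPHA3 (-2.89 ± 0.20, adjusted p = 1.11e-08), each above background on 1 of 3 SHH_10_to_18 arrays. COL1A1 (-3.20 ± 0.18, adjusted p = 1.27e-09), the neuropeptide precursor VGF (-2.86 ± 0.17, adjusted p = 2.15e-09) and EMP1 (-2.82 ± 0.22, adjusted p = 6.64e-08) fell as well. PAX6 rose by 1.01 ± 0.23 (adjusted p = 0.00964; above background on 2 of 3 SHH_6_to_18 arrays) and GLI1 by 0.85 ± 0.20 (adjusted p = 0.0128). PTCH1 fell by 0.84 ± 0.20 (adjusted p = 0.0132). NKX2-1 (0.43 ± 0.17, adjusted p = 0.138) and OLIG2 (0.02 ± 0.27, adjusted p = 0.978) did not pass, nor did LHX6 (-0.38 ± 0.22, adjusted p = 0.342), DLX2 (0.31 ± 0.22, adjusted p = 0.47) or RAX (-0.47 ± 0.28, adjusted p = 0.345).

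Postmitotic neuron genes fell in 17 of 19 and rose in 0 (17 and 0 adjusted over the list alone, camera adjusted p = 1.59e-26, adjusted p = 5.82e-05 with an estimated correlation, median -1.44). GABAergic neuron genes fell in 2 of 7 and rose in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 1e-04), GAD1 by 1.82 ± 0.19 (adjusted p = 2.37e-06). Among the 7 hedgehog targets, 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.536, median 0.10, mean -0.25 and test downward). The proliferation regulator gene MYCN rose by 1.27 ± 0.18 (adjusted p = 0.000124). Of 4 pathway genes that hedgehog signalling represses, 3 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 7.7e-05). GLI3 rose by 1.36 ± 0.21 (adjusted p = 0.00021) and GLI2 by 1.17 ± 0.21 (adjusted p = 0.00129), both above background on 2 of 3 SHH_6_to_18 arrays. Mesenchymal genes fell in 4 of 11 and rose in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 7.7e-05). Hypoxia and glycolysis genes fell in 3 of 12 and rose in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 1e-04, median -0.39), and ADM fell by 1.69 ± 0.17 (adjusted p = 2.15e-06). Cell cycle genes rose in 3 of 20 and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.000567, adjusted p = 0.0831 with an estimated correlation, median 0.39). The replication helicase subunit gene MCM5 rose by 0.96 ± 0.21 (adjusted p = 0.00611). Epithelial genes fell in 2 of 7 and rose in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.000716, adjusted p = 0.128 with an estimated correlation). Of 13 dorsal telencephalic genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0681). Of 13 immediate early genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0924). Of 12 MGE and interneuron genes, 0 changed with limma, 3 of them at an unadjusted p under 0.05 (camera adjusted p = 0.46). Neural progenitor genes rose in 2 of 14 and fell in 2 (2 and 3 adjusted over the list alone, camera adjusted p = 0.925, median 0.06, mean -0.04 and test downward).

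In total, 387 genes rose and 650 fell in SHH_10_to_18, with no overlap for 3082 genes (25.5%, where chance gives 10%). The count of 1037 became 422 with median scaling (46.2% higher in place of 37.3%), which also moved the median of all genes from 0.02 to 0.13, and 676 and 688 without SHH_6_to_18 replicate 1 or SHH_10_to_18 replicate 3. The calls of PTCH1, PAX6 and GLI1 were lost under 6, 4 and 2 of the settings tried.

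SHH_10_to_18 was compared with SHH_2_to_18 to set the latest start against the earliest. ZIC2 rose by 3.89 ± 0.18 (adjusted p = 5.48e-11, limma, 3 arrays per group) and SP8 was at least 11.0-fold higher (adjusted p = 7.29e-11). The forebrain homeobox genes OTX2 and LHX2 rose by 1.90 ± 0.18 (adjusted p = 4.19e-07) and 1.33 ± 0.20 (adjusted p = 0.000102). NKX2-2 fell by 2.56 ± 0.18 (adjusted p = 1.17e-08), FOXA2 by 2.12 ± 0.18 (adjusted p = 1.1e-07) and RAX by 2.16 ± 0.28 (adjusted p = 1.47e-05). ISL1, a LIM homeobox gene of hypothalamic and other early neurons, fell by 2.47 ± 0.24 (adjusted p = 4.29e-07). The list of the lateral and caudal eminences, which holds SP8 and ISL1, did not pass. In it, 4 of 9 members rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.224). The hypothalamic prohormone gene POMC was at least 2.93-fold lower (adjusted p = 9.09e-07) and GRP at least 23.2-fold lower (adjusted p = 8.23e-13).

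Other large rises were those of LMO3 (3.40 ± 0.16, adjusted p = 7.11e-11), WNT5B (3.15 ± 0.19, adjusted p = 1.52e-09) and SMOC1 (2.82 ± 0.26, adjusted p = 2.19e-07), each above background on 2 of 3 SHH_2_to_18 arrays. OLIG1 rose by 2.78 ± 0.21 (adjusted p = 2.51e-08). LINC01551 was at least 5.79-fold (adjusted p = 4.24e-09) and PCDH19 at least 4.92-fold higher (adjusted p = 4.24e-09). Large falls were those of COL1A1 (-3.26 ± 0.18, adjusted p = 5.36e-10), EMP1 (-3.24 ± 0.22, adjusted p = 4.92e-09), the Nodal antagonist LEFTY2 (-3.20 ± 0.23, adjusted p = 1.34e-08), CDH1 (-3.19 ± 0.19, adjusted p = 1.05e-09) and ANKRD1 (-3.14 ± 0.19, adjusted p = 1.52e-09). MMP7 fell by 3.12 ± 0.18 (adjusted p = 1.06e-09; above background on 1 of 3 SHH_10_to_18 arrays) and the translation factor gene EEF1A2 fell by 2.98 ± 0.21 (adjusted p = 6.42e-09; 2 of 3). OLIG2 rose by 1.38 ± 0.27 (adjusted p = 0.00125), PAX6 by 1.25 ± 0.23 (adjusted p = 0.000887; above background on 1 of 3 SHH_2_to_18 arrays) and GLI1 by 1.22 ± 0.20 (adjusted p = 0.00032; 2 of 3). NKX2-1 (-0.14 ± 0.17, adjusted p = 0.68), PTCH1 (-0.58 ± 0.20, adjusted p = 0.0751), LHX6 (-0.54 ± 0.22, adjusted p = 0.141) and DLX2 (0.06 ± 0.22, adjusted p = 0.916) did not pass, while the other kept probe of NKX2-1 fell by 1.04 ± 0.21 (adjusted p = 0.00176 over all kept probes).

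Hypoxia and glycolysis genes fell in 11 of 12 and rose in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 6.85e-13, adjusted p = 0.00429 with an estimated correlation, median -1.16). ADM fell by 2.14 ± 0.17 (adjusted p = 4.38e-08) and the vascular growth factor VEGFA fell by 1.60 ± 0.28 (adjusted p = 0.000489). Postmitotic neuron genes fell in 15 of 19 and rose in 0 (15 and 0 adjusted over the list alone, camera adjusted p = 7.35e-18, adjusted p = 0.000264 with an estimated correlation, median -1.32), GAP43 by 2.44 ± 0.20 (adjusted p = 6.6e-08). Epithelial genes fell in 5 of 7 and rose in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 9.94e-09). The cell adhesion gene EPCAM fell by 2.33 ± 0.21 (adjusted p = 2.18e-07). Immediate early and dissociation stress genes fell in 7 of 13 and rose in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 4.61e-06, median -0.68). JUN fell by 1.23 ± 0.19 (adjusted p = 0.00013) and FOSB fell by 1.65 ± 0.23 (adjusted p = 3.99e-05; above background on 2 of 3 SHH_10_to_18 arrays). All 4 repressed pathway genes rose (4 adjusted over the list alone, camera adjusted p = 5.95e-06), GLI2 at least 2.53-fold (adjusted p = 3.25e-06). Hedgehog targets rose in 3 of 7 and fell in 2 (3 and 3 adjusted over the list alone, camera adjusted p = 0.833, median 0.42, mean -0.20 and test downward). Mesenchymal genes fell in 3 of 11 and rose in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.167 with an estimated correlation). Neural crest genes fell in 2 of 5 and rose in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.156 with an estimated correlation). The transcription factor gene TFAP2C fell by 2.01 ± 0.24 (adjusted p = 6.14e-06; above background on 1 of 3 SHH_10_to_18 arrays). Of 12 MGE and interneuron genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.108). Of 11 hypothalamic genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.833). Of 20 cell cycle genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.833). The glutamate transporter gene SLC1A3 of radial glia rose by 2.27 ± 0.19 (adjusted p = 6.6e-08). In its progenitor list 2 of 14 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.441).

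In total, 567 genes rose and 824 fell in SHH_10_to_18, with no overlap for 3411 genes (28.2%, where chance gives 10%). Median scaling gave 767 changed genes in place of 1391 and 11 called lists in place of 7, and the neural crest list lost its call without a filter on dim probes (adjusted p = 0.0935). In none of the 6 comparisons did limma call a change among 8 housekeeping genes, and 0 of them had an unadjusted p under 0.05.

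**Figure D3:**
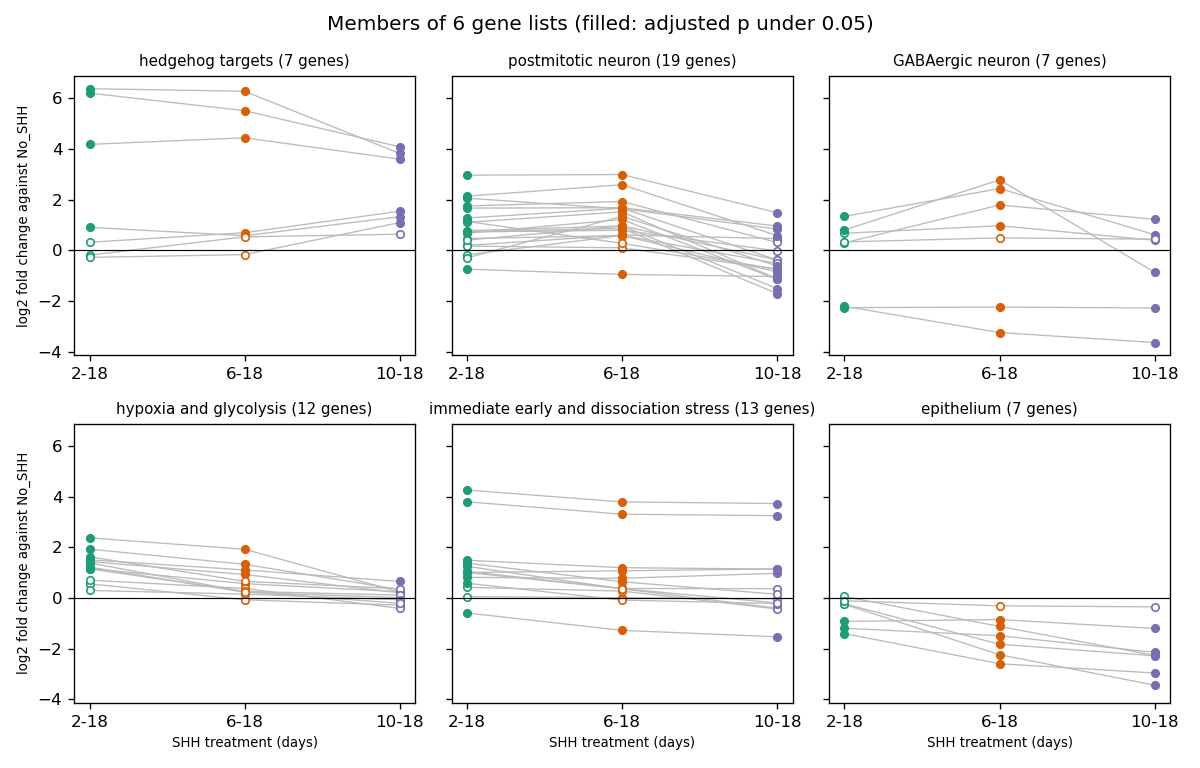
Log2 fold change against No_SHH of each measured member of 6 gene lists in the 3 SHH groups; each point is a gene, filled where its adjusted p lay under 0.05. Postmitotic neuron genes have medians of 0.73, 0.96 and -0.52 in SHH_2_to_18, SHH_6_to_18 and SHH_10_to_18. Hypoxia and glycolysis genes have medians of 1.30 in SHH_2_to_18, 0.47 in SHH_6_to_18 and 0.15 in SHH_10_to_18.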

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

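Tests on other splits of the arrays and of the differences between windows were planned before the values were seen, whereas every test of an explanation for a single pattern was chosen only after its result was seen. What singled out the genes and the list in the next paragraphs was a difference between groups: a call in opposite directions against No_SHH in 2 SHH windows, with the difference between the windows called as well (limma, 3 arrays per group). In all, 57 genes met this between SHH_2_to_18 and SHH_10_to_18, 28 between SHH_6_to_18 and SHH_10_to_18 and 9 between SHH_2_to_18 and SHH_6_to_18. Only those picked by the rule for naming genes are given, as log2 fold changes, and they need not stand for the rest.

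SHH_10_to_18 minus SHH_6_to_18 was -2.65 for STMN2, -2.58 for GAP43, -2.47 for STMN4, -2.37 for SNAP25 and -1.96 for NEFM. The interneuron peptide gene SST stood at -3.65, its probe being above background on 1 of 3 SHH_10_to_18 arrays, and the translation factor gene EEF1A2 at -1.99. SHH_10_to_18 minus SHH_2_to_18 was -2.44 for GAP43, -2.23 for STMN2, -1.82 for SNAP25, -2.98 for EEF1A2, -1.67 for SST, -1.88 for SCG2 and -2.09 for POMC (at least 2.93-fold lower). The median of the postmitotic neuron list differed by -1.44 between SHH_10_to_18 and SHH_6_to_18 and by -1.32 between SHH_10_to_18 and SHH_2_to_18. That list's call against No_SHH in SHH_10_to_18, on which its opposite direction rests, was lost with an estimated correlation (adjusted p = 0.0622).

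Other genes called in opposite directions included the forebrain factor ZIC2, at 3.89 for SHH_10_to_18 minus SHH_2_to_18. In the same difference LINC01551 stood at 3.07 (at least 5.79-fold higher), SMOC1 at 2.82, NDP at 2.63, the glial glutamate transporter gene SLC1A3 at 2.27 and EMP1 at -3.24. SHH_10_to_18 minus SHH_6_to_18 was 2.32 for LINC01551, 1.96 for SMOC1 and -2.82 for EMP1. SHH_6_to_18 minus SHH_2_to_18 was 2.05 for NDP, 2.04 for SLC1A3 and -1.88 for CAPN6. Some calls against No_SHH that make these directions opposite were lost in part of 26 settings, and 0 reversed. For SST the SHH_2_to_18 call was lost in 8 and the SHH_10_to_18 call in 6, for NEFM the SHH_10_to_18 call in 10, and for GAP43 and SNAP25 the SHH_2_to_18 calls in 6 and 4. For EMP1 and SMOC1 the SHH_6_to_18 calls were lost in 5 each, and all other such calls in at most 1.

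Probes without a single gene symbol took no part in the report's comparisons, and 5413 of them passed the detection filter. They were singled out as a signal in data the report did not use. Against No_SHH, 148 were higher and 187 lower in SHH_2_to_18, 216 higher and 278 lower in SHH_6_to_18, and 120 higher and 183 lower in SHH_10_to_18.

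The fall of postmitotic neuron genes in SHH_10_to_18 against SHH_6_to_18 might come from scaling between arrays, but the weakest list median over the other corrections and normalizations was -1.11. More cells of non-neural types would raise their own genes, yet the members of the mesenchyme, epithelium, neural crest and endothelium lists had a median of -0.37, and of 26 members 0 rose and 7 fell. This covers only the measured members of these 4 lists, and non-neural types outside them were not examined. The falls in mesenchyme and epithelium were known when the test was chosen. That there were more neural progenitors for each neuron remains possible. The neural progenitor list had a median of 0.0557, which neither shows nor excludes a modest shift. Cell cycle genes had a median of 0.39 there, with 3 of 20 rising and 0 falling (camera adjusted p = 0.000567). That call ended with an estimated correlation (adjusted p = 0.0831), so it does not settle the question. Staining of sorted cells for a neuronal and a progenitor protein would tell. A later start of neurogenesis under later SHH is the biological hypothesis, and arrays at 1 day of culture leave it open.

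The lower hypoxia and glycolysis genes in SHH_10_to_18 than in SHH_2_to_18 could reflect scaling, but the weakest list median over the other corrections and normalizations was -0.88. A single dim array could also lower them, but without any 1 of the 6 arrays the weakest median was -1.05. Culture density and oxygen were not tested here, so no biological explanation was tested.

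Against unsorted No_SHH, 10, 6 and 5 of 13 immediate early genes rose in the 3 sorted groups in window order and 1 fell in each, and the list's call in SHH_10_to_18 was lost with an estimated correlation (adjusted p = 0.0903) and in several other settings. Cell sorting and SHH itself cannot be told apart as sources of these rises, since each treated group was sorted. Between 2 sorted groups, SHH_10_to_18 and SHH_2_to_18, the list differed by a median of -0.68, so sorting as a constant addition would not account for all of them. In that comparison 7 of 13 list members fell and 0 rose (camera adjusted p = 4.61e-06). This is the same shift as the median, and it cannot separate SHH from a sorting response that differed between the groups. For SHH itself, the test asked that FOS and EGR1 be lower by over 1 on the log2 scale there, with a call. The smaller of the 2 differences was -0.53, lower but short of that size and not called (limma adjusted p = 0.114 for FOS). Arrays of sorted untreated cells, or of unsorted treated cells, would tell.

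For each of the 6 comparisons, the 6 arrays were split into 3 and 3 in all 10 ways, so the share of splits can never fall below 0.1. Every split but the real one mixes arrays of both groups, so a real difference between the groups widens its spread. The counts of the other splits therefore do not show what groups without a difference would give. In every comparison 1 of 10 splits, the real one, had as many called genes as observed (2015, 2603 and 1773 against No_SHH; 338, 1037 and 1391 between windows), and the highest other split had 0. For called lists, 1 of 10 splits again reached the real count. Real and highest other counts were 13 and 5 for SHH_2_to_18 against No_SHH, 13 and 6 for SHH_6_to_18 and 13 and 3 for SHH_10_to_18. They were 8 and 2 for SHH_6_to_18 against SHH_2_to_18, 9 and 4 for SHH_10_to_18 against SHH_6_to_18, and 7 and 4 for SHH_10_to_18 against SHH_2_to_18.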

How the results depend on the processing

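Leaving out the 2 arrays of lowest mean signal (SHH_2_to_18 replicate 1 and SHH_6_to_18 replicate 3) and leaving NKX2-1 out of its list were chosen after seeing the data; all other alternatives here were planned. Of 446 called results for named genes, 345 kept direction and call in every setting that gave a value (25 or 26), 101 lost the call in at least 1, 52 in at least 5, and 0 reversed. Of 156 list results, 0 reversed, but 104 lost a call, gained one or turned direction without a call in at least 1 setting. Over all settings, 72 calls were lost and 118 gained. The strict filter left 9516 genes to test and no filter 20041. Only 35.9% to 41.5% of probes per array were above background, and in a simulation 16 of 48 2-fold changes were recovered among simulated genes up to the median brightness and 35 of 52 above it (a division also chosen afterwards), with 42 of 52 and 46 of 48 at 4-fold. The planned fit with the slide as a block was not run, because the files name no slides.

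Median scaling gave 1130, 1524 and 1002 called genes against No_SHH for SHH_2_to_18, SHH_6_to_18 and SHH_10_to_18 (2015, 2603 and 1773 in the report), and overlaps of 820 for SHH_2_to_18 with SHH_6_to_18, 485 for SHH_2_to_18 with SHH_10_to_18 and 649 for SHH_6_to_18 with SHH_10_to_18 (1450, 889 and 1137). It gave 161 for SHH_6_to_18 against SHH_2_to_18, 422 for SHH_10_to_18 against SHH_6_to_18 and 767 with 11 lists for SHH_10_to_18 against SHH_2_to_18 (338, 1037, 1391 and 7). The higher share became 41.2% for SHH_6_to_18 against No_SHH (53.9%) and 28.6% for SHH_6_to_18 against SHH_2_to_18 (41.7%). For the latter, normexp without controls gave 511 called genes, and leaving out the 2 arrays of lowest mean signal 128. Camera with an estimated correlation called 7 lists for SHH_6_to_18 and 5 for SHH_10_to_18 against No_SHH (13 each), and 5 for SHH_10_to_18 against SHH_6_to_18 (9). Fry called 21 lists for SHH_2_to_18 and 22 for SHH_6_to_18 against No_SHH, 13 for SHH_6_to_18 against SHH_2_to_18, 17 for SHH_10_to_18 against SHH_6_to_18 and 20 for SHH_10_to_18 against SHH_2_to_18. Without background correction, genes changed at least 2-fold numbered 304, 345, 255, 34, 112 and 189 over the 6 comparisons (765, 939, 697, 146, 325 and 567), and the deposited table gave 495 for SHH_10_to_18 against SHH_6_to_18. Fewer arrays lower the power of a fit; for the other settings the cause was not tested.

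Leaving out 1 array at a time gave 1548 to 2079, 2040 to 2635 and 1351 to 1848 called genes against No_SHH in window order, with 13 to 13, 12 to 14 and 10 to 14 lists. SHH_6_to_18 against SHH_2_to_18 ran from 179 to 339 with 7 to 9 lists, SHH_10_to_18 against SHH_6_to_18 from 676 to 1008 with 9 to 11, and SHH_10_to_18 against SHH_2_to_18 from 1048 to 1447 with 7 to 8. Overlaps ran from 1128 to 1444, 653 to 929 and 886 to 1153. For SHH_6_to_18 against SHH_2_to_18, 179 came without SHH_2_to_18 replicate 1, 219 without its replicate 2 and 224 without SHH_6_to_18 replicate 1. For SHH_10_to_18 against SHH_6_to_18, 676 came without SHH_6_to_18 replicate 1 and 688 without SHH_10_to_18 replicate 3.

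With the replicate block, called genes numbered 1995, 2573 and 1740 against No_SHH and 315, 966 and 1335 between windows. The calls of the neural crest (adjusted p = 0.0545) and immediate early lists (0.0584) in SHH_10_to_18 against No_SHH ended, and no other list call did. Residuals of arrays sharing a number correlated at -0.046 to 0.049, and 4 of 12 arrays correlated best with their own number, so the numbers were not taken to pair the arrays.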

Other observations

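The 7 gene groups in this and the next paragraph, 115 genes in all, were chosen after the values were seen, and the results of all 7 are given. Of 12 retinoid metabolism genes, 2 rose and 7 fell against No_SHH in each of the 3 windows, and 0 changed between windows (limma, 3 arrays per group). The retinoic acid degrading enzyme gene CYP26A1 was at least 8.44-fold lower in SHH_2_to_18 (adjusted p = 5.76e-11), 8.32-fold in SHH_6_to_18 (adjusted p = 8.33e-11) and 8.40-fold in SHH_10_to_18 (adjusted p = 2.09e-10). RDH10, which makes retinal, was at least 6.12-fold, 6.03-fold and 6.09-fold lower (adjusted p = 5.61e-10, 1.81e-10 and 4.99e-10). The retinol receptor gene STRA6 rose by 1.72, 2.33 and 2.40 (adjusted p = 0.000141, 3.51e-06 and 2.99e-06), its probe being above background on 1 of 3 No_SHH arrays. Of 13 FGF feedback genes, 7, 9 and 10 rose against No_SHH in window order and 2, 1 and 1 fell. Between windows, 5 rose and 0 fell in SHH_6_to_18 against SHH_2_to_18, 2 and 2 in SHH_10_to_18 against SHH_6_to_18, and 8 and 0 in SHH_10_to_18 against SHH_2_to_18. ETV5 rose by 0.88, 1.21 and 1.86 against No_SHH (adjusted p = 0.00162, 5.26e-05 and 2.88e-07) and the phosphatase gene DUSP6 by 1.72, 1.85 and 1.27 (adjusted p = 2.11e-07, 7.2e-08 and 1.22e-05). Of 9 WNT ligands and inhibitors, 1 rose in each window and 5, 5 and 3 fell. Between windows, 2 rose and 3 fell, 4 and 2, and 4 and 3. DKK1 fell by 1.49 in SHH_2_to_18 (adjusted p = 9.75e-06), fell by 2.31 in SHH_6_to_18 (adjusted p = 2.99e-08) and fell by 2.50 in SHH_10_to_18 (adjusted p = 1e-08), above background on 2 of 3 arrays of each of the later windows. Of 12 ZIC and other transcription factor genes, 2, 1 and 2 rose and 6, 5 and 3 fell. Between windows, 2 rose and 1 fell, 5 and 0, and 5 and 1. LMO3 fell by 2.94 in SHH_2_to_18 (adjusted p = 1.35e-10; above background on 2 of 3 arrays), fell by 1.51 in SHH_6_to_18 (adjusted p = 1.16e-06) and differed by 0.46 in SHH_10_to_18 (adjusted p = 0.0674).

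Of 18 neuropeptide and secretory granule genes, 10, 8 and 4 rose against No_SHH and 2, 2 and 4 fell. SHH_10_to_18 had 1 higher and 8 lower than SHH_6_to_18, and 1 higher and 9 lower than SHH_2_to_18, while SHH_6_to_18 had 1 higher and 4 lower than SHH_2_to_18. VGF rose by 3.02 in SHH_2_to_18 (adjusted p = 1.53e-10) and 3.13 in SHH_6_to_18 (adjusted p = 8.05e-11) and differed by 0.27 in SHH_10_to_18 (adjusted p = 0.334). The orexin precursor gene HCRT went the other way, at least 1.18-fold, 1.89-fold and 4.93-fold higher (adjusted p = 0.0449, 7.54e-05 and 5.73e-09). Of 8 Notch pathway genes, 3, 3 and 1 rose against No_SHH and 2, 1 and 2 fell. Between windows 0 rose, and 1 fell in SHH_6_to_18 against SHH_2_to_18, 3 in SHH_10_to_18 against SHH_6_to_18 and 3 in SHH_10_to_18 against SHH_2_to_18. HEY1 rose by 2.93 in SHH_2_to_18 (adjusted p = 1.53e-10) and 1.71 in SHH_6_to_18 (adjusted p = 2.6e-07) and differed by -0.01 in SHH_10_to_18 (adjusted p = 0.976). DLL3, which encodes a Notch ligand, rose by 2.23, 2.46 and 1.26 (adjusted p = 6.85e-08, 1.5e-08 and 0.000106). Of 18 interferon response genes, 2, 4 and 3 rose and 2, 1 and 2 fell. Between windows, 1 rose and 0 fell, 0 and 2, and 1 and 3. IFIT1 rose by 1.23, 3.31 and 3.67 (adjusted p = 7.1e-05, 9.18e-11 and 4.28e-11) and IFITM1 by 2.85, 2.63 and 1.26 (adjusted p = 2.12e-09, 6.57e-09 and 0.000114). EPSTI1 was at least 5.18-fold, 5.11-fold and 5.15-fold lower (adjusted p = 7.04e-09, 1.49e-09 and 1.06e-09).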
